A study of Mus musculus with 27 samples.

How the data were processed

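Total RNA of 9 mouse tissues, 3 samples each, was labelled with biotin and hybridised to a custom 1-colour Affymetrix array for glycogenes, per the labels and the series' design text. The deposited table holds 1 intensity per probe set and array on a linear scale, for 1813 probe sets and 27 arrays. The summary method, background correction, scaling between arrays and detection calls that the authors used are not given in the sources used here. The arrays had nearly equal medians over all probe sets, from 221.5 in bone marrow replicate 3 to 243.7 in testis replicate 1, as scaled values do, but not equal distributions. Values were therefore kept as deposited in the main analysis, with other scalings as alternatives. No 2 arrays held identical values.

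Probe sets were named through the platform annotation, in which 1563 had 1 gene symbol, 2 had several and 248 had none and stayed unnamed. Mouse genes were matched by gene identifier to RefSeq (assembly GRCm38.p6), which updated 1 symbol and was used for names and neighbouring genes and not for coordinates, since no build is named for the array. The 702 probe sets whose gene identifier matched a mouse gene gave 573 genes. Control probe sets and 839 human probe sets were left out of the tests, and the latter served to describe cross-species background. Intensities under 16 were raised to 16 (2 values, 0.0129% of all) and log2 taken. For a gene with several probe sets, the one with the highest mean over all arrays was kept. In 122 genes with several probe sets, the tissue means of the other probe sets correlated with the chosen one with a median r of 0.836, and 15 genes had a negative correlation.

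limma 3.58.1 in R 4.3.3 was fitted with 1 coefficient per tissue over all arrays (lmFit and eBayes). The 9 tissues were compared by the moderated F test, each tissue against the equal-weight mean of the other 8, the 4 lymphoid and blood-forming tissues against the other 5, and the 36 tissue pairs with each other. Benjamini-Hochberg adjustment ran over genes within each contrast, and a gene was called at an adjusted p under 0.05 with an absolute log2 difference (for the F test, a range of tissue means) of at least 1. Folds are powers of 2 of these differences, so that they compare with a geometric mean of the other tissues. The 39 gene lists, 13 of them markers of cell types, were fixed before the data were examined, as were the design, the alternatives and the rule for named genes. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over all lists and contrasts.

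The rule named, for the F test, the 10 called genes with the largest range and the 5 with the smallest range among genes above the median level. For each tissue it named up to 8 called higher genes whose lowest array lay above all arrays of the other tissues, and up to 3 called lower genes whose highest array lay below them. For the lymphoid contrast it named up to 10 genes in each direction with all 4 tissue means on the same side of the other 5. It also named all measured terminal epitope enzymes and up to 4 called members of each called list. A few genes outside it are marked in the text as named after their values were seen.

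The script was tested on simulated data for liver against the other 8 tissues, with 200 of 573 genes changed: it called 100% of genes changed by 1.5, 2 or 3 on the log2 scale, 0% of those changed by 0.5, which lies under the threshold on size, and 0 of the 373 unchanged genes. The F test called 98% of genes changed by 1.5. In a simulated list test, 1 of 210 tests of lists without changed genes was called. The simulated reference tissues did not differ and no change lay near the threshold, so that this checks the script and not its power on the real data. Alternatives were quantile normalization, median centring, leaving out the 191 genes with the lowest mean, a floor of 64, an offset of 16 without a floor, the mean of a gene's probe sets, eBayes with trend and robust settings, array weights, the title number as a block, the median of the other 8 tissues as the reference, and leaving out each of the 27 arrays. The T cell marker list without Ccl25, tested with its 4 other measured genes, was added after seeing the data.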

Results

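Transcript levels of glycan-related and immune genes were measured in 9 tissues of wild-type male C57BL/6 mice, an inbred laboratory strain, aged 6 to 8 weeks. The tissues were bone marrow, brain, kidney, liver, lung, lymph node, spleen, testis and thymus, with 3 arrays each and 27 arrays in all. The array was a custom Affymetrix design for glycogenes, the genes whose products build, carry, bind or degrade glycans, together with chemokine, cytokine and growth factor genes. After 1 probe set per gene was kept, 573 mouse genes were compared. Values below are deposited intensities given as mean ± SD of the 3 arrays of a tissue, and differences are on the log2 scale with their SE from limma. The number of arrays, not a read depth, limits the precision, and no label says that the 3 arrays of a tissue came from separate animals, so that p-values measure only the spread between arrays. All 27 arrays correlated best with an array of their own tissue. The median correlation across genes was 0.976 between arrays of the same tissue (0.931 to 0.988) and 0.612 between arrays of different tissues (0.420 to 0.914). Human probe sets on the same array were taken as a rough measure of cross-species background. They had a median intensity of 205.2 with a 95th percentile of 590.1, and mouse genes had a median of 296.8. Levels in that range are not separated from non-specific signal by this measure. A fold with such a level on one side is a ratio of signals, not an exact ratio of transcripts.

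Genes with large ranges among tissues included Ltf, Ugt2b5, Igf1 and Reg1. Ltf, the iron-binding lactoferrin of neutrophil granules, spanned 6.48 on the log2 scale (89.0-fold) and peaked in bone marrow (14124 ± 802). Ugt2b5 and Ugt1a6a, UDP-glucuronosyltransferases, spanned 81.5-fold and 61.4-fold and peaked in liver at 8716 ± 2073 and 5567 ± 1282. Clec4a2, a C-type lectin receptor of myeloid cells, spanned 74.8-fold with its peak in bone marrow. Igf1, insulin-like growth factor, spanned 54.9-fold with its peak in liver, and Reg1, a secreted lectin-like protein, spanned 53.0-fold with its peak in spleen. Ltb (52.5-fold) and Cd48 (40.1-fold), genes of lymphocyte signalling and adhesion, peaked in lymph node, Cd74, the invariant chain of antigen presentation, peaked in spleen (46.2-fold), and the sialyltransferase St6galnac2 peaked in testis (44.6-fold). The lowest tissue means of these 10 genes, 38.2 to 184.1, lay below the human probe set median of 205.2, so that their lowest tissue is not settled and the spans are not exact. At the other end, Hs6st3, Ifnab, Fzd5, B4galt5 and Ccr8 had the smallest ranges among genes above the median level, between 1.16-fold and 1.21-fold, with adjusted p of 0.210 to 0.334. With limma's moderated F test, 287 of the 573 genes differed among the 9 tissues at the set threshold and with a range of at least 1. Clec4a2 spanned 32.0-fold with all probe sets of a gene averaged and 40.4-fold with a floor of 64, and St6galnac2 spanned 69.98-fold with quantile normalization. Probe sets of the Ugt1a and Ugt2b families can bind transcripts of related family members, and the other B4galt5 probe set did not follow the chosen one (r = -0.38 over tissue means).

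**Figure D1:**
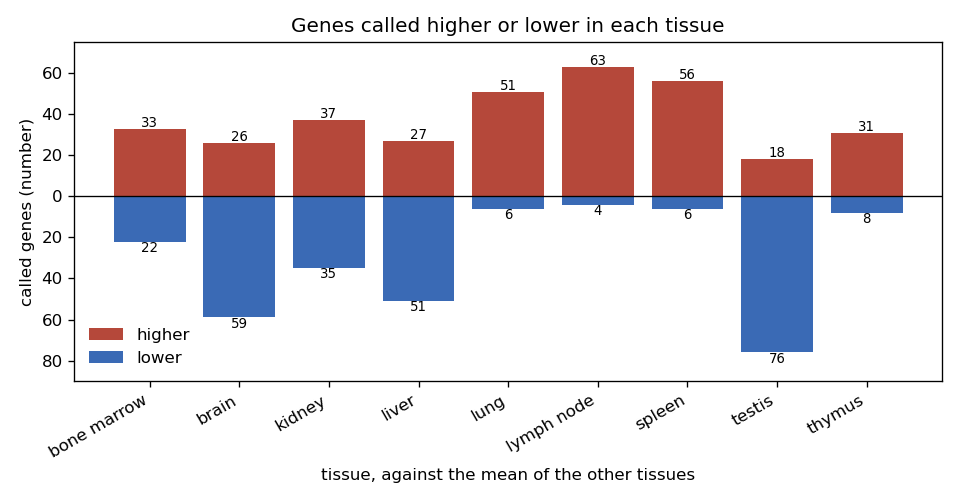
Number of genes called higher (bars above 0) or lower (bars below 0) in each tissue against the mean of the other 8 tissues, out of 573 genes. Lymph node had 63 higher and 4 lower, and testis had 18 higher and 76 lower.

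In bone marrow, Ltf and markers of neutrophils stood above the other tissues. Ltf reached 14124 ± 802 and was higher by 5.76 ± 0.27, or 54.3-fold (limma adjusted p = 1.93e-14), than the mean of the other 8 tissues. Clec4a2 (16.6-fold), the neutrophil-attracting chemokine Cxcl2 (16.4-fold), the monocyte chemokine receptor Ccr2 (12.5-fold) and Clec7a, the beta-glucan receptor dectin-1 (9.00-fold), followed. Junb, an AP-1 transcription factor subunit, was 5.62-fold higher, Lta4h, which makes leukotriene B4, 4.25-fold, and Csf3r, the receptor of granulocyte colony-stimulating factor, 3.51-fold. Among the 5 measured neutrophil and granulocyte precursor markers, Csf3r and Cxcr2 (2.36-fold) rose and Cd33, Clec5a and Siglece were not called. The list as a set was higher (camera adjusted p = 0.00168, and adjusted p = 0.225 with an estimated correlation). Markers of other blood cells moved beside it. Of 6 macrophage and monocyte markers 2 rose and 1 fell (mean 0.91, camera adjusted p = 0.499). Of 4 B cell markers 1 rose, and of 3 megakaryocyte and platelet markers 1 rose. Below all other arrays in bone marrow were the small proteoglycans Dcn (257.5 ± 9.0, 8.09-fold lower) and Bgn (6.05-fold lower), and the lymphoid chemokine Ccl21b (5.58-fold lower), whose near-identical copies the probe set may not separate. Of 21 measured proteoglycan core proteins, Srgn (3.98-fold) rose and Dcn, Bgn and Fmod (2.83-fold) fell, Srgn and Fmod being named after their values were seen, and the list was not called (camera adjusted p = 0.499). In all, 33 genes were higher and 22 lower, with 12 of the higher and 6 of the lower outside the range of all 24 other arrays. Chance would put 0.0342% of genes on either side if all arrays were independent. Arrays of the same tissue are not, so that this share is too low to serve as a reference. With the median of the other 8 tissues as the reference, 14 genes were lower, and with probe sets averaged Csf3r was 12.0-fold higher.

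Brain had higher levels of Ptn, Cx3cl1 and genes of glycosphingolipid synthesis. Ptn, the heparin-binding growth factor pleiotrophin, reached 1450 ± 343 and was higher by 3.46 ± 0.11 (11.0-fold, limma adjusted p = 5.58e-18), and Cx3cl1, the chemokine fractalkine, reached 2407 ± 111 and was 10.1-fold higher. Fgf12 (5.44-fold), the imprinted gene Peg3 (5.40-fold), the globoside synthase B3galnt1 (4.34-fold), the exostosin-like Extl2 (3.84-fold), Chga, the secretory granule protein chromogranin A (3.49-fold), and the ganglioside sialyltransferase St3gal2 (2.56-fold) were also above every other array. Of 16 measured glycosphingolipid and ganglioside genes, 4 rose and none fell: Ugt8a, which makes galactosylceramide (11.3-fold), B3galnt1, St3gal2 and the lactosylceramide synthase B4galt6 (2.55-fold). The set was higher (camera adjusted p = 0.0180, and adjusted p = 0.225 with an estimated correlation). Of 11 neural glycan genes, Ugt8a and the fucosyltransferase Fut9 (3.60-fold, at 148.3 ± 47.6, a level below the human probe set median of 205.2) passed the test (camera adjusted p = 0.0363, and adjusted p = 0.429 with an estimated correlation). Of 5 neuron and glia markers, Ugt8a rose, and Mag, Ncan, Bcan and St8sia3 were not called (camera adjusted p = 0.00657, and adjusted p = 0.120 with an estimated correlation). The glycosphingolipid, neural glycan and marker lists share Ugt8a, so that their calls are not independent of each other. Ugt8a was higher still in kidney (613.8 to 757.5) than in brain (414.5 to 575.3). Of 26 fibroblast growth factor genes and receptors, Fgf12 was the 1 that rose (camera adjusted p = 0.0290, and adjusted p = 0.225 with an estimated correlation). Ugt1a6a (8.30-fold), Cd48 (7.34-fold) and the galactosyltransferase B4galt1 (4.14-fold) were lower than on all other arrays. Of 31 C-type lectins and collectins, 7 fell and none rose, led by Clec4a2 (7.74-fold lower), the mannose receptor Mrc1 (4.90-fold), Clec7a (4.72-fold) and Ly75 (2.90-fold), with a camera adjusted p = 0.0109 and adjusted p = 0.412 with an estimated correlation. Leukocyte markers, named after their values were seen, were lower beside them: Mrc1, Clec7a and Ccr2 (4.71-fold) of 6 macrophage and monocyte markers (mean -1.10, camera adjusted p = 0.499), Il7r (2.35-fold) and Ccr7 (2.68-fold) of 5 T cell markers (mean -0.75, camera adjusted p = 0.163) and Fcer2a (2.05-fold) of 4 B cell markers, where Mrc1, Clec7a and Fcer2a are also on the lectin list. In all, 26 genes were higher and 59 lower, and quantile normalization gave 38 and 49. St3gal2 lost its call when probe sets were averaged (0.98), where Clec4a2 was 3.996-fold lower (4.33-fold with a floor of 64), and Fut9 and Ly75 lost theirs with a floor of 64 (0.82 and -0.77). Ugt8a was 5.79-fold higher with that floor and 17.7-fold against the median of the other tissues, and Cx3cl1 was 15.5-fold higher with quantile normalization. The growth factor set lost its call without brain replicate 2, with quantile normalization and with array weights, and the neural glycan set lost its call with median centring. When the lowest genes were left out, 15 genes were higher, and the glycosphingolipid, lectin, neural glycan and growth factor sets all lost their calls.

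Kidney had higher levels of Ugt8a, Fut9 and genes of lysosomal glycan degradation. Ugt8a reached 685.7 ± 71.8 (15.9-fold higher) and Fut9, which completes the Lewis x epitope, reached 451.0 ± 80.6 (12.9-fold higher, 3.69 ± 0.20, limma adjusted p = 1.68e-13). Their lists were not called: of 16 glycosphingolipid and ganglioside genes Ugt8a and B3galnt1 (2.15-fold, named after its value was seen) rose and B4galnt1 fell (camera adjusted p = 0.690), and of 10 fucosyltransferases Fut9 was the 1 that rose (camera adjusted p = 0.801). Of 18 measured genes of lysosomal glycan degradation, 5 rose and none fell: the sialidase Neu1 (2305 ± 288, 7.79-fold), the beta-galactosidase Glb1 (3.48-fold), the sulfatase Galns (3.35-fold), the galactosylceramidase Galc (2.92-fold) and Aga (2.35-fold), the last named after its value was seen. The set was higher (camera adjusted p = 0.0238, and adjusted p = 0.627 with an estimated correlation). Of 22 genes of nucleotide sugar synthesis and transport, 4 rose: Papss2 (3.11-fold) and Papss1 (2.07-fold), which make the sulfate donor PAPS, the UDP-GlcNAc transporter Slc35a3 (2.65-fold) and Ugdh, which makes UDP-glucuronic acid (2.14-fold). Their set had a camera adjusted p = 0.0202 and an adjusted p = 0.668 with an estimated correlation. The glypican Gpc4 (2.61-fold), Renbp, an N-acetylglucosamine epimerase (2.58-fold), and Bmp7 (2.42-fold) were also above every other array. Vcam1, an endothelial and stromal adhesion molecule, was 3.05-fold lower and the ganglioside synthase B4galnt1 2.90-fold lower than the mean of the others. Of 31 C-type lectins and collectins, 5 fell: Clec4a2 (4.35-fold), Mrc1 (3.53-fold), Clec7a (2.81-fold), the IgE receptor Fcer2a (2.27-fold) and Cd72 (2.22-fold, named after its value was seen), with a camera adjusted p = 0.0290 and adjusted p = 0.530 with an estimated correlation. Leukocyte markers were lower beside them, the added ones named after their values were seen: Mrc1, Clec7a and Ccr2 (2.08-fold) of 6 macrophage and monocyte markers (mean -0.84, camera adjusted p = 0.145), Il7r (2.32-fold) and Ccr7 (2.31-fold) of 5 T cell markers (mean -0.73, camera adjusted p = 0.0845), and Fcer2a and Cd72 of 4 B cell markers, where Mrc1, Clec7a, Fcer2a and Cd72 are also on the lectin list. The 1 measured kidney epithelium marker was not called in kidney (log2 difference 0.16) and was called higher in brain (1.31) and spleen (1.33). In all, 37 genes were higher and 35 lower. With a floor of 64, Ugt8a was 8.12-fold and Fut9 6.30-fold higher. The lectin set lost its call without kidney replicate 1, and Papss1 fell under the threshold without kidney replicate 2 (0.96). When the lowest genes were left out, the lysosomal, nucleotide sugar and lectin sets all lost their calls. With the median of the other 8 tissues as the reference, Fcer2a (-0.34) and Papss1 (0.96) were not called, and Ugt8a was 23.9-fold higher.

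Liver had higher levels of Ugt2b5, Igf1 and all measured hepatocyte markers. Ugt2b5 reached 8716 ± 2073 and was higher by 5.39 ± 0.28 (41.9-fold, limma adjusted p = 5.79e-14), Igf1 reached 4057 ± 404 (17.2-fold higher), and Ugt1a6a was 12.4-fold higher. Asgr2, a subunit of the hepatic asialoglycoprotein receptor, was 13.0-fold higher at 1587 ± 240, and Mbl1, a mannose-binding lectin of plasma, 10.5-fold higher at 2555 ± 279. All 3 measured hepatocyte markers rose, the last being Mbl2 (6.07-fold); the list was too short to be tested. Egfr (8.47-fold), Igfbp2 (8.41-fold) and the leukemia inhibitory factor receptor Lifr (8.14-fold) were also above every other array. The other Lifr probe set did not follow the chosen one (r = -0.49 over tissue means), and their average was 2.77-fold higher. Tmsb10, an actin-binding thymosin, was 8.09-fold lower, the hexokinase Hk1 3.80-fold lower at 182.6 ± 3.4, below the human probe set median of 205.2, and Cd83, a marker of activated dendritic cells, 3.74-fold lower (2.26-fold against the median of the other tissues). In all, 27 genes were higher and 51 lower, with 20 of the higher and 9 of the lower outside the range of all other arrays.

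Lung had higher levels of Thbd and of lung epithelium and endothelial markers. Thbd, the endothelial anticoagulant receptor thrombomodulin, reached 5593 ± 1113 and was higher by 4.63 ± 0.10 (24.8-fold, limma adjusted p = 4.24e-21). Both measured lung epithelium markers rose: Cxcl15, the chemokine lungkine, was 21.0-fold higher at 7886 ± 3062, and Sftpd, the collectin surfactant protein D, was 20.8-fold higher at 8312 ± 1758 (59.1-fold with probe sets averaged). Of 5 endothelial markers, 4 rose and Sele was not called. They were the angiopoietin receptor Tek (14.7-fold), Pecam1 (12.0-fold), Cd34 (5.54-fold) and Emcn (5.32-fold), and the set was higher (camera adjusted p = 8.75e-04, and adjusted p = 0.225 with an estimated correlation). The adhesion molecule Icam2 (11.0-fold), the receptor Acvrl1 (9.81-fold) and Bgn (9.60-fold) were also above every other array. The 5 measured T cell markers were lower as a set in lung, with differences of -0.83 to -0.16 that were all under the size threshold (camera adjusted p = 0.0488, and adjusted p = 0.567 with an estimated correlation), a call kept under 15 of 35 alternatives, lost without any 1 of 16 arrays and lost without Ccl25 (adjusted p = 0.119). In all, 51 genes were higher and 6 lower, and 35 of the higher genes lay above all other arrays. Cxcr5, the B cell chemokine receptor, was the 1 lower gene outside the range of the other arrays (2.01-fold lower, -1.01 ± 0.08), at the edge of the threshold: it was -0.98 with quantile normalization, -0.91 without lung replicate 3 and -0.55 against the median of the other tissues. The lower calls were 3 when the lowest genes were left out and 3 against that median.

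**Figure D2:**
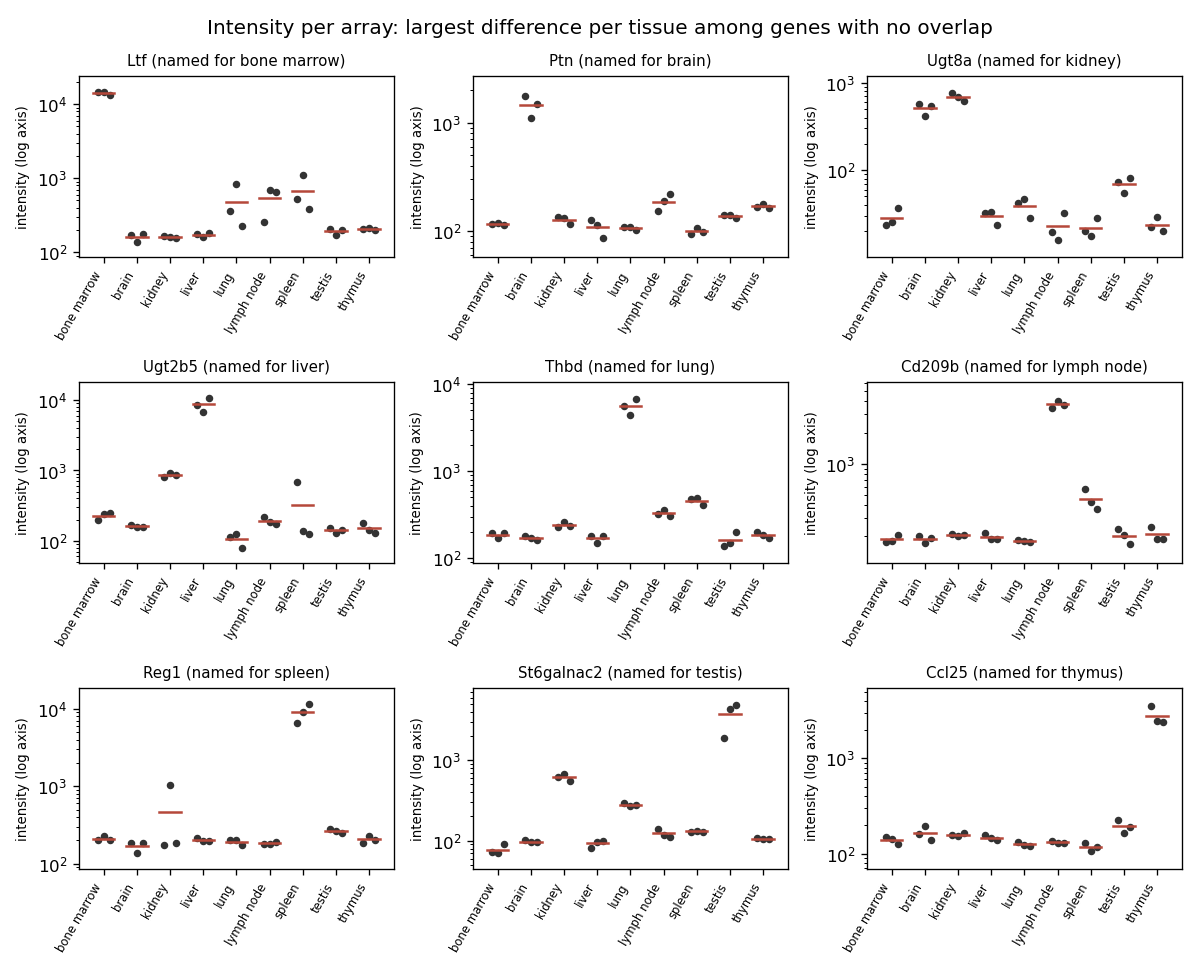
Intensity (log axis) on each array of the gene with the largest log2 difference among genes above all other arrays, for each of the 9 tissues; points are the 3 arrays of a tissue and lines their mean. Each named gene lies highest in its tissue, such as Ltf in bone marrow (mean 14124) and Reg1 in spleen (mean 9082), where kidney replicate 2 reads 1045 for Reg1 against 176.2 and 186.9 in the other kidney arrays.

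Lymph node had the most genes higher than the mean of the other tissues, except with quantile normalization, where lymph node and spleen both had 48. Cd209b, a SIGN-R1 C-type lectin of macrophages, reached 3743 ± 288 and was higher by 4.11 ± 0.10 (17.3-fold, limma adjusted p = 6.28e-20). Glycam1, the sulfated mucin-like ligand of L-selectin made by high endothelial venules, reached 4306 ± 298 and was 16.2-fold higher. The chemokines Ccl5 (12.2-fold), Ccl8 (11.8-fold), Ccl21b (10.6-fold, at 9377 ± 1069) and Cxcl9 (5.86-fold) rose, as did lymphotoxin beta, Ltb (12.5-fold), and the interleukin 7 receptor Il7r (5.85-fold). Of 4 measured B cell markers, 3 rose: Fcer2a (7.68-fold), Cd72 (3.69-fold) and Cxcr5 (3.02-fold). Markers of other cell types rose beside them, with none of these lists called as a set. They were 2 of 5 T cell markers (mean 0.90), 3 of 6 macrophage and monocyte markers (mean 0.81) and 1 of 5 endothelial markers (mean 0.57). The 26 fibroblast growth factor genes and receptors were lower as a set with none called singly (camera adjusted p = 0.0424, and adjusted p = 0.225 with an estimated correlation). They lost the call without lymph node replicate 3, with quantile normalization, with median centring, with array weights and with the lowest genes left out. In all, 63 genes were higher and 4 lower, the latter being Ugt8a, Fut9, Galnt3 and Ugt1a6a, named after their values were seen. Ugt8a (22.7 ± 8.9) and Fut9 (24.7 ± 3.9) were near the bottom of the scale there. With probe sets averaged, Ccl5 was 4.70-fold and Glycam1 9.93-fold higher, and against the median of the other 8 tissues Ltb was 29.1-fold and Ccl21b 21.0-fold higher. The lower calls came to 2 without lymph node replicate 1, 2 without lymph node replicate 2, 1 against the median of the other tissues and 9 with median centring.

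Spleen had higher levels of Reg1, Reg2, Vcam1 and 3 of the 4 measured B cell markers. Reg1 reached 9082 ± 2404 and was higher by 5.37 ± 0.28 (41.3-fold, limma adjusted p = 1.07e-13), and Reg2, of the same family, was 8.01-fold higher at 2929 ± 2033, with spleen replicate 1 at 583.4 and the other arrays at 4194 and 4009; without replicate 1 it was 15.3-fold higher. Vcam1 (6.75-fold, 4278 ± 425), the mannose receptor Mrc1 (4.72-fold, 1361 ± 23), Cxcr5 (3.95-fold), the interleukin 10 receptor Il10ra (3.61-fold) and the collagen Col14a1 (3.08-fold) were above every other array. Of 3 measured megakaryocyte and platelet markers, Pf4, platelet factor 4, rose (6.01-fold) and Itga2b and Selp were not called. The other Pf4 probe set did not follow the chosen one (r = -0.43 over tissue means), and their average was 2.36-fold higher. The B cell markers that rose were Fcer2a (5.74-fold), Cd72 (3.95-fold) and Cxcr5, and this list and the platelet list were too short to be tested. Of 6 macrophage and monocyte markers, Mrc1 and Clec7a (2.05-fold, named after its value was seen) rose, and the list was not called (camera adjusted p = 0.499). In all, 56 genes were higher and 6 lower, and against the median of the other tissues the lower calls came to 1.

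Testis had more lower than higher genes, and the largest rise was that of St6galnac2. St6galnac2, a sialyltransferase of O-glycans, reached 3722 ± 1594 and was higher by 4.57 ± 0.16 (23.7-fold, limma adjusted p = 5.94e-17). Itgae, the integrin subunit CD103, was 8.45-fold higher at 2744 ± 833, Galnt3, which starts O-glycans, 6.34-fold at 1915 ± 102, and the mucin Muc3 5.62-fold. Mpi (4.63-fold), which interconverts mannose and fructose phosphates, and Gfpt1 (3.83-fold), which starts hexosamine synthesis, were also above every other array, as were Gps2 (2.59-fold) and the elongation factor Tcea1 (2.39-fold). The leukocyte integrin Itgb2 was 8.46-fold lower at 83.1 ± 8.8, a level below the human probe set median of 205.2, the polysialyltransferase St8sia4 6.66-fold lower and Ugdh 6.62-fold lower. No list was called in testis. Of 6 polypeptide GalNAc transferases Galnt3 rose and Galnt1 (2.27-fold) and Galnt2 (2.18-fold) fell (camera adjusted p = 0.903), and of 11 genes of mucin-type core extension St6galnac2 rose and B3gnt2 (2.33-fold) fell (camera adjusted p = 0.499). Of 6 macrophage and monocyte markers Clec7a (3.70-fold) and Ccr2 (3.97-fold) fell (camera adjusted p = 0.532), of 5 T cell markers Il7r (2.12-fold) fell (camera adjusted p = 0.625), and of 4 B cell markers none was called. These lower list members were named after their values were seen. In all, 18 genes were higher and 76 lower, with 25 of the lower genes below all other arrays. Testis replicate 1 had control probe set ratios (3' over 5' end) of 3.73 for actin and 4.13 for Gapdh, where the other 26 arrays stayed at or below 1.81 and 2.10. Without it, 19 genes were higher and 71 lower, and 84 of these 90 calls were among the 94. With quantile normalization St6galnac2 was 36.01-fold, Galnt3 9.83-fold and Mpi 7.05-fold higher, and Itgb2 was 14.6-fold lower against the median of the other tissues. None of the marker genes of male germ cells on the fixed list was measured.

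Thymus had higher levels of Ccl25 and its receptor Ccr9. The chemokine Ccl25 reached 2794 ± 641 and was higher by 4.25 ± 0.10 (19.0-fold, limma adjusted p = 2.47e-20), and Ccr9, carried by developing T cells, reached 2063 ± 325 (12.1-fold higher). The costimulatory receptor Cd27 (5.61-fold), the lectin Ly75 of thymic epithelium and dendritic cells (4.72-fold), the antiproliferative gene Btg2 (4.202-fold), the integrin Itgal (3.93-fold) and the polypeptide GalNAc transferase Galnt7 (2.37-fold) were also above every other array. Of 5 measured T cell markers, Ccl25 and Ccr9 rose, and the set was higher (camera adjusted p = 3.55e-05, and adjusted p = 0.120 with an estimated correlation). Ccl25 is made by thymic epithelium and not by T cells. Without it, an alternative chosen after seeing the data, the 4 other markers were higher as a set (camera adjusted p = 0.00311, and adjusted p = 0.225 with an estimated correlation), and Ccr9 was the 1 called. In all, 31 genes were higher and 8 lower, and no lower gene lay below all other arrays. The lower calls came to 5 when the lowest genes were left out and 2 against the median of the other tissues.

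The 4 lymphoid and blood-forming tissues (bone marrow, lymph node, spleen, thymus) had higher levels of Ltb, Itgb2 and Cd48 than the other 5. Ltb was higher by 4.67 ± 0.07 (25.4-fold, limma adjusted p = 2.32e-24), the leukocyte integrin Itgb2 17.4-fold, Cd48 13.0-fold and the chemokine Ccl5 7.85-fold. Selplg, the P-selectin ligand PSGL-1, was 7.54-fold higher and St8sia4 7.20-fold, followed by Tgfb1 (5.85-fold), Btg2 (4.85-fold), Il7r (4.66-fold) and Il17ra (4.57-fold). Lower in these tissues were Ugt8a (5.15-fold), the growth factor Fgf1 (2.34-fold) and Cxcl15 (2.01-fold). Of 42 chemokines and receptors, 12 rose, among them Ccl5, Ccr2 (5.98-fold), the B cell chemokine Cxcl13 (5.59-fold) and Ccr7 (4.08-fold), and 3 fell. The set had a camera adjusted p = 0.0456 (adjusted p = 0.627 with an estimated correlation) and lost its call without any 1 of 5 arrays: bone marrow replicate 2, kidney replicate 1, kidney replicate 2, spleen replicate 3 and testis replicate 3. It also lost its call when the lowest genes were left out. Of 5 T cell markers, Il7r, Ccr7 and Ccr9 (2.02-fold) rose (camera adjusted p = 0.0420, and adjusted p = 0.567 with an estimated correlation), a call lost with array weights and without Ccl25 (adjusted p = 0.104). Of 4 B cell markers, Fcer2a (3.69-fold), Cd72 (3.35-fold) and Cxcr5 (2.04-fold, permutation p = 0.119) rose. Of 6 macrophage and monocyte markers 3 rose (mean 0.99, camera adjusted p = 0.456), and of 3 megakaryocyte and platelet markers 1 rose. In all, 62 genes were higher and 15 lower. The limma error covers the spread between arrays and not between tissues. In the exact two-sided permutation of the 9 tissue means into 4 and 5, Ccr7 had p = 0.00794, the smallest it can give, Ccr2 p = 0.0238, Cxcl13 p = 0.0556 and Ccr9 p = 0.103. The first 10 higher genes and the 3 lower genes given above were named because all 4 tissue means lay on the same side of the other 5, so that this permutation is no independent evidence for them, and Ugt8a (p = 0.0556) and Cxcl15 (p = 0.413) missed the threshold even so. For 27 of the higher and 3 of the lower genes the 4 tissue means lay all above or all below the other 5. Chance would put 0.794% of all genes on either side if the 9 tissues were independent. The 27 and 3 were counted among called genes only, and lymph node, spleen and thymus are alike (median correlations of 0.844 to 0.889), so that this share does not serve as a reference. With probe sets averaged, Ccl5 was 3.18-fold higher, and with a floor of 64 Ugt8a was 2.49-fold lower. Ccr9 (0.94 with array weights) and Cxcl15 (-0.96 without lung replicate 2) fell under the threshold under several alternatives and with other arrays left out.

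Of 14 measured enzymes that finish terminal glycan epitopes, 7 differed among tissues by the F test with a range of at least 1. Fut9 spanned 19.96-fold (6.97-fold with a floor of 64 and 12.03-fold with an offset of 16 and no floor), from 22.9 in lung to 451.0 ± 80.6 in kidney, with 148.3 ± 47.6 in brain. Its levels outside kidney lay below the human probe set median of 205.2. The peaks of Fut9, Cmah, Sec1, Fut7 and Chst4 all lay below the human 95th percentile of 590.1, so that their levels are not separated from non-specific signal by that measure. Lymph node arrays still lay above every other array for Cmah (499.2 to 635.1, next liver replicate 3 at 474.2). The same held for Chst4 (275.2 to 337.3, next lung replicate 3 at 262.5). For Sec1 and Fut7 the arrays of the highest tissue overlapped with those of other tissues. On the Fut9 probe set itself, kidney arrays read 381.3 to 539.3 and brain arrays 117.5 to 203.2. No array of another tissue read above 46.7, so that kidney, brain and the rest do not overlap for Fut9. B4galnt1 spanned 6.12-fold and was highest in spleen (1323 ± 251) and lymph node (1275 ± 126.1). St3gal6, which sialylates galactose in selectin ligands, spanned 4.85-fold and peaked in lung (971.4 ± 195.0). St6gal1, which makes the alpha2,6-sialylated ligand of Cd22, spanned 4.23-fold with nearly equal levels in lymph node (890.0 ± 94.3) and spleen (886.4 ± 39.6). Cmah, which makes N-glycolylneuraminic acid, spanned 2.66-fold and peaked in lymph node. Sec1 (2.04-fold, highest in testis) and Fut7, a selectin ligand fucosyltransferase (2.02-fold, highest in bone marrow at 451.6 ± 76.4), were at the edge of the threshold: the range of Fut7 was 0.88 without bone marrow replicate 3, 0.97 without brain replicate 1 and 0.99 with quantile normalization, and that of Sec1 was 0.92 without testis replicate 3, 0.98 without testis replicate 2 and 0.99 without lung replicate 1. Chst4, the high endothelial venule sulfotransferase, spanned 0.93 and was highest in lymph node (303.4 ± 31.4); its range was 1.002 without lymph node replicate 3, past the threshold. Mgat3, Fut4, Fut1 and Fut2 had ranges of 0.32 to 0.61 with adjusted p of 0.00128 to 0.0185, and Abo and B4galnt2 had adjusted p of 0.0589 and 0.562. The probe sets of St6gal1 (lowest r = 0.11) and Fut2 (r = -0.15) did not follow each other, and with probe sets averaged St6gal1 spanned 2.63-fold.

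**Figure D3:**
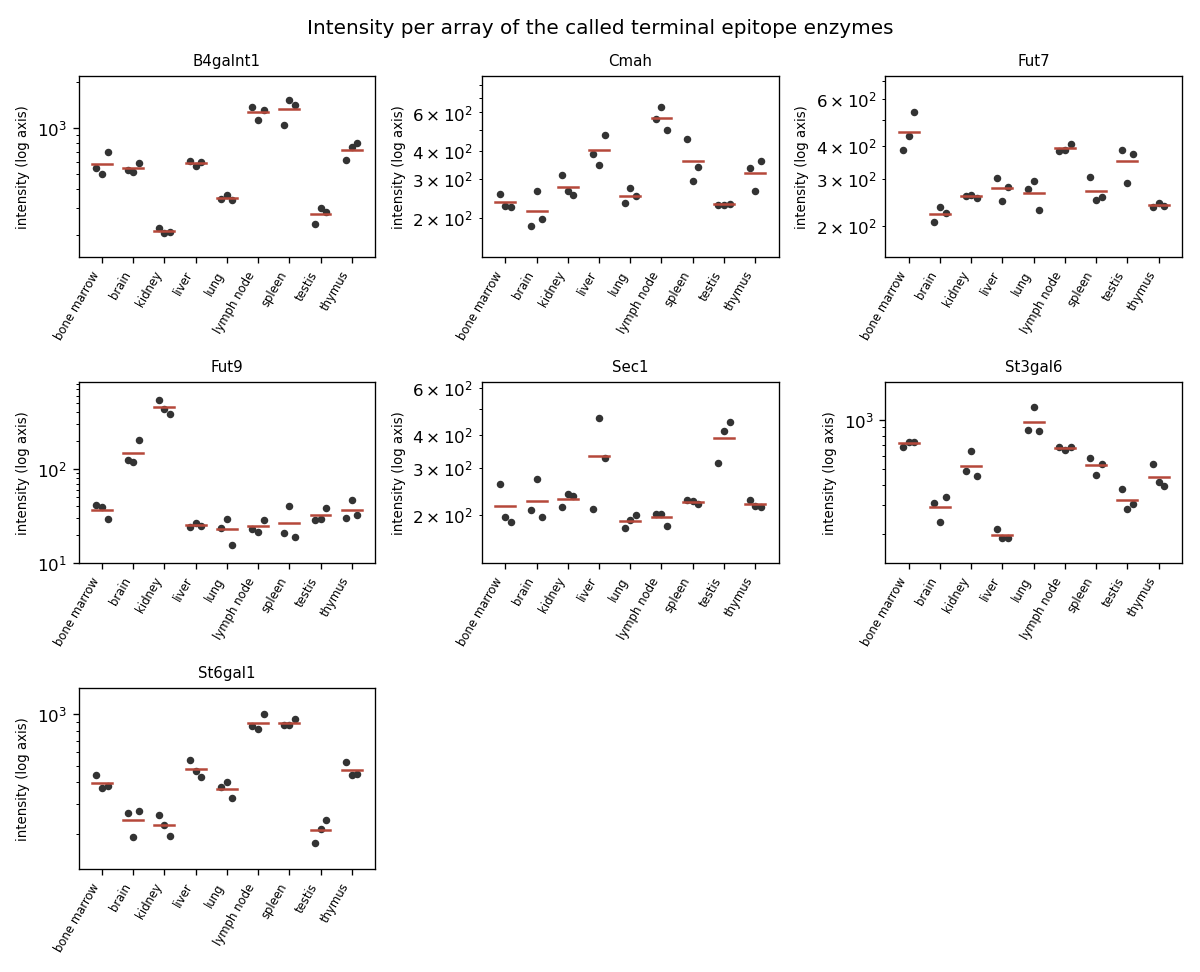
Intensity (log axis) on each array of the 7 terminal epitope enzymes called by the F test; points are the 3 arrays of a tissue and lines their mean. Fut9 is highest in kidney (mean 451.0), and St6gal1 and B4galnt1 are highest in lymph node and spleen.

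Over all 27 lists with at least 5 measured genes and the 10 contrasts, 15 of 270 camera tests were called with the preset correlation and 0 with an estimated one, where 20 had an unadjusted p under the threshold. With the lowest genes left out, 1 test was called, and without Ccl25 among the T cell markers 13. Counts of called members adjusted over the list alone equalled those over all genes for each of the lists named above.

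The tissues closest to each other were lymph node and spleen, with 24 genes called between them, 14 higher in lymph node and 10 higher in spleen. Spleen and thymus (45 genes), bone marrow and thymus (48) and lymph node and thymus (51) followed. The order by median correlation between arrays was another one. Lymph node and spleen (0.889) were again closest, followed by lymph node and thymus (0.856), spleen and thymus (0.844) and bone marrow and thymus (0.781). Brain and lymph node were farthest apart with 133 genes, 30 higher in brain and 103 higher in lymph node. Among the non-lymphoid tissues, kidney and liver (61 genes) and brain and testis (65) differed least, and lung and testis most (123, of which 104 were higher in lung).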

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

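The 37 alternatives were fixed before the data were examined, and 1, the T cell markers without Ccl25, was added after seeing the data and gave 13 called list tests, all 13 among the 15. No named result changed direction under any of the 37. This was largely fixed in advance, since ranges of tissue means cannot change sign. Most other genes were named for large differences, many with no overlap of arrays. Of 5541 values of 151 named results under the alternatives, 5493 stayed on their side of the threshold, 47 fell under it, all with the same direction, and 1 rose above it, over 11 results given in the report. The count over the F test was 208 to 298 under the alternatives in processing, where the lowest value comes from testing fewer genes, and 285 to 293 with 1 array left out. With the lowest genes left out, and thus fewer genes tested, 15 genes were higher in brain, 3 lower in lung, 2 lower in lymph node and 5 lower in thymus. In that setting 1 of the list tests was called, the neutrophil set in bone marrow. The other called sets lost their call or were too short to be tested. The set calls thus depend on the low genes being included, for a reason that was not tested. The lower calls in lymph node were 9 with median centring, which moved the median difference there by -0.0997, 2 with a floor of 64 and 2 with an offset of 16 and no floor; the cause was not tested. Against the median of the other 8 tissues, 14 genes were lower in bone marrow, 3 in lung, 1 in lymph node, 1 in spleen and 2 in thymus; the cause was not tested. With 1 array left out, the lower calls in lymph node ranged from 2 to 4. Median centring moved the median difference over all genes by -0.10 in lung, -0.11 in spleen and 0.10 in testis. Lymph node and spleen had the fewest called genes under all 36 alternatives that refit the pairs, and brain and lymph node the most under 35; with array weights lymph node and testis had the most (133).

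Array numbers in the titles recur in every tissue, but same-numbered arrays did not deviate together: 25 of 108 same-number pairs had a correlation of deviations over 0.1 (mean -0.0021, range -0.37 to 0.55), and 8 of 27 arrays correlated best with their own number. With the number as a replicate block, the F test called 287 genes, and the calls in each of the 9 tissues were the same genes. Signal over background limits the low end: levels up to the human probe set 95th percentile of 590.1 are not separated from non-specific signal by that measure. Folds against such levels are uncertain, as is their order where arrays of the tissues overlap. The measure is rough, since it sets 1 cutoff for all probe sets. Human probe sets may also hold signal from mouse transcripts, which was not tested: those for ribosomal proteins had medians from 270.1 in brain to 614.3 in bone marrow. A level under the cutoff is thus not shown to be non-specific. On a single probe set the order can still be read where arrays lay apart, as for Fut9 in kidney and brain and for Cmah and Chst4 in lymph node.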

Other observations

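The tests of the patterns below were chosen after the results were seen, except the camera tests, whose lists and design were fixed before.

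Several glycan gene groups that were not called as sets held members that passed the test singly; the members given here were picked after their values were seen. In testis, of 18 genes of lysosomal glycan degradation, 5 were lower and 2 higher (camera adjusted p = 0.651). The lower ones were Ctsa, the protective protein of lysosomal sialidase (5.88-fold), Neu1 (4.29-fold), the beta-glucuronidase Gusb (3.21-fold), Man2b1 (3.03-fold) and Manba (2.35-fold), and the higher ones were Galc (2.69-fold) and Arsa (2.10-fold), which act on galactosylceramide and its sulfated form. Of 22 genes of nucleotide sugar synthesis and transport, 4 were higher in testis (Mpi, Gfpt1, Slc35a3, Hk1) and 3 lower (Ugdh, Galt, Papss1), with a camera adjusted p = 0.7999. The rise of Hk1 rested on testis replicates 2 and 3 (7940 and 3201), with 493.7 on replicate 1. In lymph node, 5 of 21 proteoglycan core proteins were higher and none lower: Dcn (4.75-fold), serglycin, Srgn (4.05-fold), Fmod (3.20-fold), Lum (2.86-fold) and Bgn (2.60-fold), with a camera adjusted p = 0.921.

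Human probe sets for ribosomal proteins, left out of all comparisons, read higher in the 4 lymphoid and blood-forming tissues. Of 22 such probe sets, 19 had a log2 difference above 0 and 12 one of at least 1, with a median of 1.02 (range -0.21 to 1.91). An exact two-sided permutation of their median profile over the tissues gave p = 0.00794, the smallest it can give, but the group was picked after its values were seen, so that this p is no independent evidence. Of the 817 other human probe sets, 6 reached 1, with a median of -0.08. Median levels were 614.3 in bone marrow, 582.5 in spleen, 560.6 in lymph node and 497.7 in thymus, against 270.1 in brain to 393.2 in lung.

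Reg1, Reg2 and Reg3b, genes abundant in exocrine pancreas, were high in spleen, and a candidate source is pancreatic tissue taken with the spleen, which lies beside it. Of 19 pancreas genes listed for this test, these 3 were measured, so that abundant digestive enzymes could not be checked. Above the background of the other tissues, spleen replicate 1 reached 63.97% of the mean of the other spleen arrays for Reg1 (6658 against 9125 and 11464), 8.37% for Reg2 and 2.19% for Reg3b (166.7 against 1197 and 1138), so that the largest share was 29.2 times the smallest, where tissue of a constant makeup predicts like shares. Reg1 also read 1045 in kidney replicate 2, against 176.2 and 186.9 in the other kidney arrays. The ceiling of the Reg1 probe set is unknown, where the highest intensity of any probe set was 26096. Reg3b in spleen replicate 1 was below the highest array of another tissue (279.9). For these reasons pancreatic tissue and expression in the spleen cannot be told apart. Expression in the spleen was not tested.

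Itgae was higher in testis than in any lymphoid tissue, by 3.42 on the log2 scale over the mean of brain, kidney, liver and lung. Leukocytes in the testis samples would bring their other transcripts, but 6 leukocyte genes (Itgb2, Itgb7, which encodes the partner chain of Itgae, and the T cell markers without Ccl25) had a median difference of 0.045 on that scale and a highest of 0.36, and Itgb2 was at -1.13. Clec4a2, a myeloid receptor outside these 6 genes, went the other way and was 3.07-fold higher in testis than the mean of the other 8 tissues. In RefSeq, Haspin, a kinase gene of male germ cells, lies within the bounds of Itgae. Only these bounds were compared, and not strand, exons or probe sequences, so that it is open whether a Haspin transcript can reach the Itgae probe set at all. The array has 0 probe sets named for Haspin and 1 for Itgae, so that the genes cannot be told apart here. Expression of Itgae by testis cells was not tested.

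The share of higher calls was 94.0% in lymph node and 19.1% in testis, a gap of 74.9 percentage points (73.0 to 77.9 with 1 array left out). Scaling of the deposited values is not the whole cause, since the gap was 62.6 with quantile normalization and 62.5 with median centring. Against the median of the other 8 tissues the gap was 74.5, with the p-values of the contrast with their mean kept. For testis, 4 of those 8 tissues are lymphoid or blood-forming, so that the median does not remove their joint pull. High values in some of the other tissues are therefore not excluded as a cause. A choice of immune genes for the array may account for part of it: among the 128 genes of the glycan enzyme lists that are on no immune, lectin or cell marker list, lymph node had 8 higher and 2 lower and testis 10 higher and 19 lower, a gap of 45.5, with 10 calls in lymph node too few to decide. Such a choice and a difference in cell makeup between the tissues, which was not tested, cannot be told apart here.

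Chance as the source of the calls was examined by regrouping the samples. Over 100 splits of the 27 arrays into groups of 3, the real one included, 1 split, the real one, gave as many calls for each count of genes: 287 genes by the F test (highest other 47), 55 in bone marrow (33), 85 in brain (15), 72 in kidney (7), 78 in liver (5), 57 in lung (25), 67 in lymph node (11), 62 in spleen (11), 94 in testis (42) and 39 in thymus (11). Arrays of the same tissue had a median correlation of 0.976, against 0.612 between tissues. A regrouping of single arrays therefore mixes unlike tissues, and the outcome was largely fixed in advance. These counts do not exclude chance differences between the animals or samples behind a tissue. The gene list tests came to 15 in the real split and to 14 in another, a margin of 1 test, and to 12 to 15 with 1 array left out, so that chance is not excluded for that count either. For the lymphoid contrast, 100 splits that keep tissues whole gave 77 in the real split and at most 74 in another one drawn. That other split set brain, kidney, lung and testis against the rest. It kept the 4 lymphoid and blood-forming tissues together and moved only liver to their side. Being close to the real split, it does not show that unlike groupings differ by nearly as many genes. Not all possible splits were drawn, so that 74 need not be the highest. The pairs of lymph node and spleen (24 genes, highest other 0) and of brain and lymph node (133, highest other 0) have 10 splits each, too few for a share under 0.05.

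Single arrays stood apart for some genes, given here as values. Hk1 read 493.7, 7940 and 3201 on the 3 testis arrays. Ugt2b5 read 696.2 in spleen replicate 1 against 136.2 and 123.9 in the other spleen arrays. Clec4a2 read 1121, 364.9 and 473.4 in testis. The values that stood apart in testis for Hk1 and Clec4a2 include those of replicate 1, given first, the array with the high control probe set ratios.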
